A study of Mus musculus with 4 samples.

How the data were processed

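Gene expression was measured in cultured adherent cells of the mouse spleen on 4 Affymetrix arrays, 2 of colony-forming cells (SACCs) and 2 of monolayer controls. Per the labels' protocols, total RNA was extracted with a column kit and turned into biotinylated cRNA by the array maker's protocol. The deposited values are log2 expression per probe set, in 2 tables of a SACC array and its control each. Transcriptome Analysis Console is named in the submitters' processing notes without a version, and the summarisation, background correction, normalization and genome build are not given in the sources used here. Within a table the sorted values of the 2 arrays differed by at most 0.14 and 0.2, and across tables by 0.27 to 0.32, so the 2 tables appear normalized separately and all ratios were taken within a table. A table of all 4 arrays deposited with the series held the same values, so using it in place of the tables could not change a value and was not run. The arrays have no counted depth, and their number limits the precision. Pearson correlations were 0.967 and 0.972 within the pairs, 0.97 between the SACC arrays, 0.959 between the controls, and 0.946 and 0.947 for the remaining combinations, so no arrays were duplicates.

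Groups, media and pairs came from the labels, which name a control array as the reference of each SACC array. That statement is the source of the pairing, and with only 2 pairs it was not tested on the values. Symbols came from the tables: of 45037 probe sets 36109 had a single symbol, 1236 several and 7628 none, and 64 held a date in place of a symbol. Of the single symbols 33553 were current and 1116 were synonyms in a RefSeq gene table (GRCm38.p6), used for names only, and 1440 were not in it and kept the name of the file. Probe sets with several symbols were not named. For named genes and lists a gene was represented by its probe set with the highest mean over the 4 arrays, which gave 19747 genes; of 9058 genes with several probe sets, 3731 had probe sets of both signs.

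The test over both pairs was limma 3.58.1 (R 4.3.3), lmFit and eBayes with default settings on the log2 values, with group and pair as terms and Benjamini-Hochberg adjustment over all 45037 probe sets, none filtered, at 0.05. It had 1 residual degree of freedom, moderated by 2.97 prior degrees of freedom and a prior SD of 0.181. Ratios within a pair rest on 1 array per group and were counted at 2-fold, and between pairs at 4-fold, without a test; the number expected from independent pairs is the product of the pairs' shares. Before the data were examined, 39 gene lists were written, with 499 entries, of which 481 were measured; 18 genes had no probe set named for them. Lists were tested with limma's camera (preset correlation 0.01) and fry on the blocked design, with Benjamini-Hochberg adjustment over the 39 lists, and described in each pair by the percentile of the list median among 10000 random lists matched on mean expression in 20 bins. Camera compares the genes of a list with all other genes, and its preset correlation treats the genes of a list as nearly independent. Its p-values with that preset therefore do not measure the spread between samples. Camera's estimated correlation rests on the single residual degree of freedom.

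Named genes followed a rule written before the data were examined. It took genes with a single symbol, at least 1 of 4 values above the array's median and a symbol that is not a predicted model, clone name, small RNA, olfactory or vomeronasal receptor, or immunoglobulin or T cell receptor segment. It then took the 12 highest and 12 lowest mean ratios past the test with the same sign in both pairs, up to 4 members of each list with the largest mean ratio, the 8 largest differences between the pairs in each direction, and Csf1r, Ptprc, Col1a1, Pou5f1 and Mki67 in any case, 188 entries in all. Some other list members, such as Lyz2, Col3a1, Acta2 and Egr1, are named as examples chosen after their values were seen. Each ± is the moderated standard error of limma's fit over 2 pairs, which draws on all probe sets and not only on the gene's own 2 ratios.

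The procedure was tested on simulated data with the prior variance of these arrays and 45037 probe sets. With 200 of them changed, 0, 6, 80.6 and 91.6% were recovered at log2 changes of 1, 2, 3 and 4, with 7.68% false calls on average. With 4500 changed the shares were 48.6, 95.4, 98.8 and 99.3%, with 5.1% false calls. The simulated noise was independent between probe sets and the change was the same in both pairs. In the real arrays whole lists moved together, so these shares of false calls need not hold for them. Alternatives planned before the data were examined were the fit without the pair block, each array centred on its median, quantile normalization over the 4 arrays, only probe sets above the median probe set, eBayes with a trend or robust, an adjusted p of 0.10, 1 probe set per gene, the mean of a gene's probe sets, camera with an estimated correlation, folds of 1.5 and 4, and leaving out each array without the block. An adjusted p of 0.04 was added after the values were seen. The count over both pairs was therefore computed in 14 ways in all, and the setting fixed in advance is the main result whatever the others gave. A further 4 gene lists were written for the closing part after the first results, each before its own test. Figures were drawn with matplotlib 3.10.9.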

Results

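Splenic adherent cells that pile up into tight colonies (SACCs) were compared with adherent cells of the mouse spleen that had stayed in a monolayer, the controls. Both came from cultured spleen pieces of C57BL/6J mice, and total RNA was measured on 4 Affymetrix arrays, 2 of SACCs and 2 of controls. SACC replicate 1 had been kept in a serum-free embryonic stem cell (ES) medium and SACC replicate 2 in plain medium, as had both controls. The labels name a control as the reference of each SACC array. These give an ES pair (SACC replicate 1 and control replicate 1) and a plain pair (SACC replicate 2 and control replicate 2). Array medians on the log2 scale were 4.52 and 4.59 for the SACC and control arrays of the ES pair, and 4.35 and 4.34 for those of the plain pair. Ratios below are log2 SACC minus control within a pair, so a ratio of 1 is a 2-fold higher level in SACCs. Nothing in the labels says that the samples came from separate animals or cultures, so p-values of single genes can reflect only the spread between these samples, which may be technical. Camera's p-values for lists compare genes with other genes and do not measure that spread. In the test over both pairs the spread between samples is the difference between the pairs' ratios, so it also holds any effect of the SACC medium. Limma draws each probe set's spread toward a value shared by all probe sets. A standard error below is therefore not that gene's own spread alone. Clec7a, with a ratio of -2.25 in both pairs, still has a standard error of 0.16. The number of arrays limits the precision, and no detection calls were used, so folds against values below an array's median are uncertain.

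The first comparison asked which genes differed between SACCs and monolayer cells in both pairs. All 20 fibroblast and matrix genes on a list fixed in advance were higher in SACCs in both pairs, and all 18 macrophage genes were lower. Igfbp5, a secreted binding protein of insulin-like growth factors, had the highest mean ratio among genes past the test, 6.19 ± 0.16 (SE, n = 2 pairs). This is a 73-fold difference, although the control value of the plain pair, 2.64, lay below its array's median. The imprinted noncoding RNA H19 was 13.4-fold higher (3.74 ± 0.16) and Mfap4, a microfibril-associated protein, 12.6-fold higher (3.65 ± 0.26). Rgs1, a regulator of G protein signalling, was 11.4-fold lower, with a mean ratio of -3.5 ± 0.23. Ptprc, the common leukocyte antigen CD45, had ratios of -2.08 in the ES pair and -2.04 in the plain pair.

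The other genes of the 12 highest were Asic3 (4.84), an acid-sensing ion channel, the chemokines Cxcl3 (4.71) and Cxcl5 (3.71), the aminopeptidase Enpep (4.32), the proprotein convertase Pcsk5 (4.14), Itm2a (4.11), Lgi2 (3.74), the heparan sulfate sulfotransferase Hs3st1 (3.67) and the interferon-inducible GTPase Iigp1 (3.61). The control values of Asic3, Cxcl3 and Pcsk5 lay below the array medians in both pairs. The others of the 12 lowest were Cytip (-3.35), the interleukin 7 receptor Il7r (-3.08), Tspan13 (-3.02), Csf2rb2 (-2.96), a receptor subunit for interleukin 3, and the oxysterol receptor Gpr183 (-2.96). Stap1 (-2.95), the Rac-inactivating Arhgap25 (-2.92), the T cell costimulator Cd28 (-2.87), the adaptor Pik3ap1 (-2.87), Pkib (-2.81) and Hnmt (-2.77), which methylates histamine, completed them. For Pcsk5, 1 of its 5 probe sets went the other way.

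**Figure D1:**
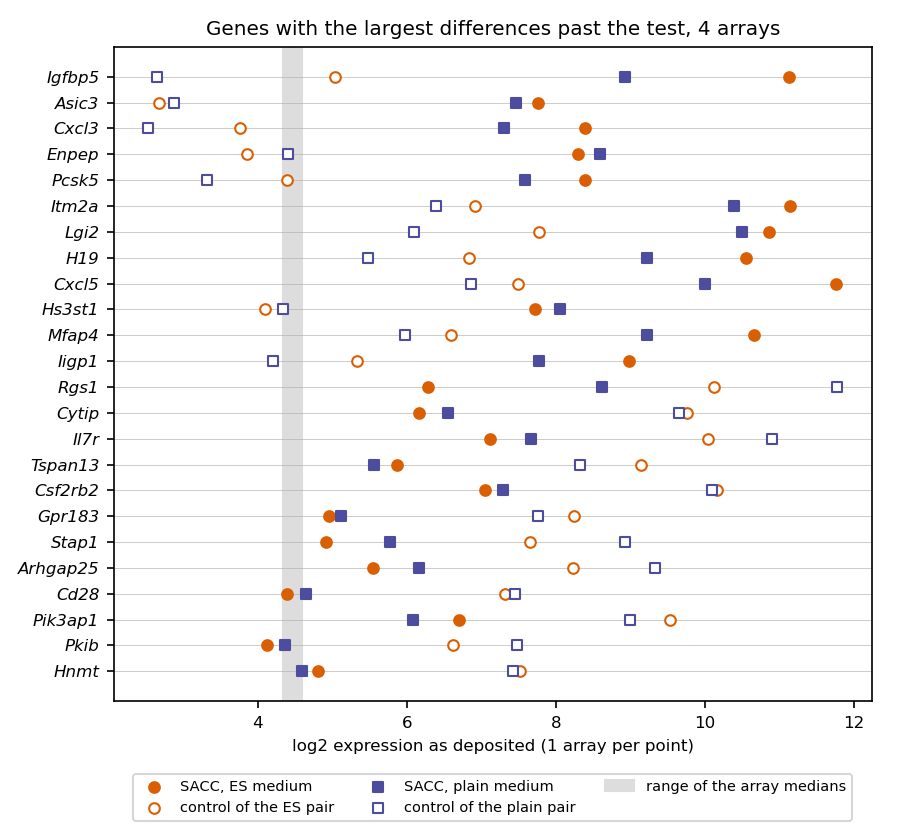
Log2 expression as deposited (x axis) of the 12 highest and 12 lowest genes past the test over both pairs; each point is 1 array, filled for SACC and open for control, circles for the ES pair and squares for the plain pair, and the grey band spans the array medians (4.34 to 4.59). The tables of the 2 pairs appear normalized separately, so distances are to be read within a pair; Igfbp5 lay at 11.13 and 8.93 on the SACC arrays against 5.04 and 2.64 on their controls.

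In limma with the pair as a block and Benjamini-Hochberg adjustment, 587 of 45037 probe sets passed an adjusted p of 0.05, 289 higher and 298 lower in SACCs, in 461 genes. The smallest adjusted p was 0.0476, shared by 403 of the 587, so the calls lay just inside the threshold. No probe set passed with each array centred on its median (limma, smallest adjusted p 0.0636; 7405 at an unadjusted p under 0.05) or without the pair as a block (limma, smallest adjusted p 0.16; 3497 unadjusted). Counted without a test, 1940 probe sets differed at least 2-fold in the same direction in both pairs, 1070 higher and 870 lower, where independent pairs would give 105 and 63.9. Across probe sets, which are not independent replicates, the ratios of the 2 pairs correlated with Pearson's r = 0.593 and Spearman's rho = 0.427, and r was 0.663 among probe sets whose mean exceeded that of the median probe set.

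Macrophage genes were lower in SACCs in both pairs. All 18 measured genes of the macrophage list had negative ratios in both pairs, with medians of -1.79 in the ES pair and -1.77 in the plain pair, and 17 were at least 2-fold lower in both. Of these, 7 fell and 11 did not pass the test over all probe sets; adjusted over the list alone, 18 fell. The colony-stimulating factor receptor Csf1r (-1.75 ± 0.17, SE, n = 2 pairs), the lipid-sensing receptor Trem2 (-2.42 ± 0.16) and the F4/80 antigen Adgre1 (-2.34 ± 0.17) were among the 7. Lysozyme, Lyz2, remained at 13.27 and 13.36 on the SACC arrays, with ratios of -0.68 and -0.55. Its control values, 13.95 and 13.91, lay close to the maxima of those arrays (14.11 and 14.24), so these ratios may be compressed. In limma's camera with its preset correlation the list was called lower with a Benjamini-Hochberg adjusted p of 2.4e-15 over 39 lists, against an adjusted p = 0.847 with an estimated correlation. The small value comes from treating the list's genes as nearly independent. In fry the list's adjusted p was 0.0982.

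Genes of lysosomes and lipid handling, many of them abundant in macrophages, were lower in both pairs for 16 of 16 members, with medians of -1 and -1.17. Gpnmb (-1.84 ± 0.16) and the lysosomal acid lipase Lipa (-1.68 ± 0.16) fell; adjusted over the list alone, 13 fell. Camera gave the list an adjusted p of 3.8e-09 after Benjamini-Hochberg adjustment and an adjusted p = 0.847 with an estimated correlation. Erythroid genes (medians -0.37 and -0.3) and genes of antigen presentation on MHC class II (-0.38 and -0.39) were also called lower by camera, with Benjamini-Hochberg adjusted p of 0.0122 and 0.0297, and for both the adjusted p = 0.847 with an estimated correlation. No erythroid member passed the test over all probe sets and 1 fell adjusted over the list alone; the list's largest value was that of the transferrin receptor Tfrc (-1.4), which many dividing cells express, and 5 of its 8 members lay below the median on every array. None of the 9 MHC class II genes passed by either adjustment, and H2-Aa had ratios of -1.93 and -0.62.

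Fibroblast and matrix genes showed the opposite pattern. All 20 were higher in SACCs in both pairs, with medians of 1.32 and 1.65, and 16 were at least 2-fold higher in both. Col1a1, a chain of type I collagen (2.3 ± 0.16, SE, n = 2 pairs), the matrix protein Postn (1.78 ± 0.16), the fibroblast activation protein Fap (1.66 ± 0.16) and Col6a1 (1.59 ± 0.16) rose, and 16 did not pass the test over all probe sets; adjusted over the list alone, 20 rose. The proteoglycan Lum had a mean ratio of 1.87 ± 0.22 with a limma adjusted p of 0.058. Camera called the list higher with a Benjamini-Hochberg adjusted p of 2.4e-15, against an adjusted p = 0.847 with an estimated correlation. In fry the list's adjusted p was 0.256. The controls of both pairs also held much collagen RNA, with Col3a1 at 13.14 and 12.13.

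**Figure D2:**
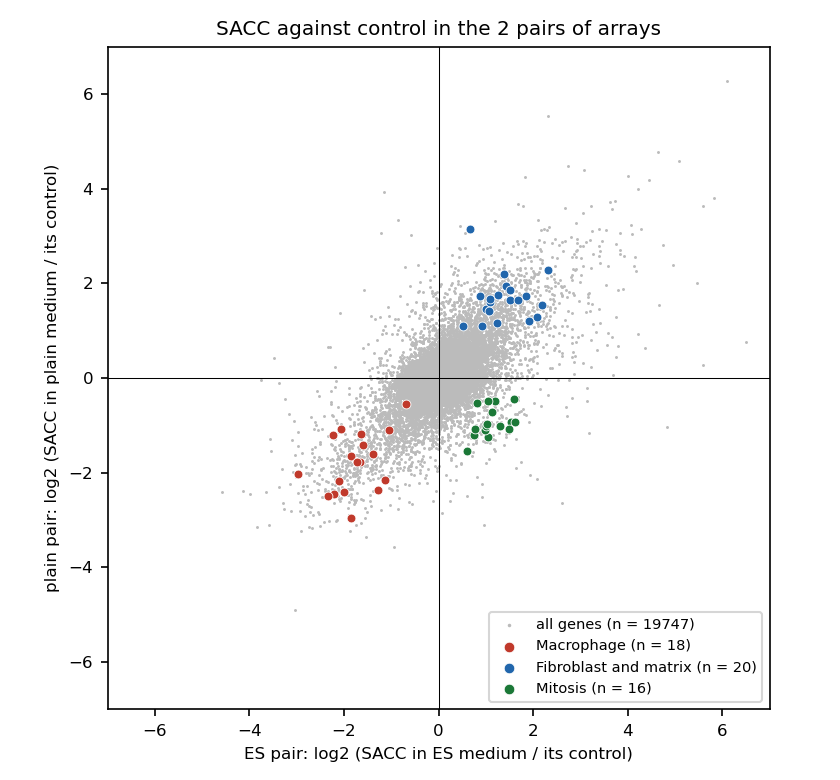
Log2 ratio of SACC to control in the ES pair (x axis) against that in the plain pair (y axis) for 19747 genes (grey), with the macrophage (red), fibroblast and matrix (blue) and mitosis (green) lists; each point is 1 gene. Macrophage genes lie in the lower left (medians -1.79 and -1.77), fibroblast and matrix genes in the upper right (1.32 and 1.65), and mitosis genes in the lower right (1.04 and -1).

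Further stromal lists had medians above 0 in both pairs. Smooth muscle and myofibroblast genes had medians of 1.21 and 0.51 and were higher in both pairs for 11 of 12 members; Rgs5, a pericyte marker, rose by 2.98 ± 0.26 (SE, n = 2 pairs) and was the only member to pass by either adjustment, over all probe sets or adjusted over the list alone. The muscle intermediate filament Des had ratios of 4.21 and 0.93, while Acta2, at 12.71 or above on all 4 arrays, had ratios of 0.18 and 0.13. Lymphoid stromal cell genes had medians of 0.73 and 0.34. Tcf21, a transcription factor of splenic mesenchyme, rose by 1.94 ± 0.18, and 4 members rose adjusted over the list alone. Of 11 measured, 8 were higher in both pairs and 1, Mfge8, was lower in both (-0.41 and -1.57). Cxcl13 had ratios of 0.01 and 0.15, and Ccl19, Ccl21a and Fdcsp were not measured. Wt1, shared with the mesothelial list, had a mean ratio of 3.23 ± 0.34 with a limma adjusted p of 0.0508, and the spleen-forming factor Tlx1 ratios of 3.35 and 0.6. Mesothelial genes had medians of 1.17 and 0.28, with 3 of 10 higher adjusted over the list alone and none over all probe sets. Of the 10, 7 were higher and 2 lower in both pairs. The 2 lower ones, Msln and Muc16, were among 4 members that lay below the median on every array. Mesenchymal transition factors had medians of 0.69 and 1.12; Snai1 rose by 2.12 ± 0.16, and adjusted over the list alone 6 rose and 2 fell. Camera's Benjamini-Hochberg adjusted p were 0.000154 for smooth muscle, 0.0122 for mesothelial, 0.0252 for lymphoid stromal and 0.0272 for transition genes. For these 4 lists the adjusted p = 0.847, 0.847, 0.887 and 0.847 with an estimated correlation.

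The fatty acid synthesis list, the interferon response list and the list of p53 targets and senescence genes were also called higher by camera. Scd1, a fatty acid desaturase, rose by 2.43 ± 0.24 (SE, n = 2 pairs); the synthesis list had medians of 0.76 and 0.34, and 2 of 10 members rose adjusted over the list alone. Interferon-inducible Ifi44 rose by 3.56 ± 0.3 from control values below the array medians. Of the 15 members of its list 4 rose adjusted over the list alone, with medians of 0.87 and 0.12. The median of the plain pair lay at percentile 79.7 of random lists. In both pairs 9 members were higher and 2 lower. Another 4 were higher in the ES pair and lower in the plain pair, such as Rsad2 (0.46 and -1.39). Of the p53 targets and senescence genes none passed over all probe sets and 2 rose adjusted over the list alone. The list medians were 0.27 and 0.39, and that of the ES pair lay at percentile 83.4 of random lists. Of 12 members 7 were higher in both pairs. The cyclin-dependent kinase inhibitor Cdkn2b had ratios of 1.14 and 1.55 and Phlda3 0.75 and 1.08. Mdm2 (0.26 and -0.03) and Bax (0.11 and -0.27) were not higher in both. Camera's Benjamini-Hochberg adjusted p were 0.00322, 0.0272 and 0.0252 for fatty acid, interferon and p53 genes. With an estimated correlation no list was called, and for these 3 the adjusted p = 0.847, 0.932 and 0.847 with an estimated correlation. Without the pair block, camera's calls for interferon, MHC class II, lymphoid stromal and p53 genes were lost on leaving out control replicate 1 (Benjamini-Hochberg adjusted p 0.396, 0.216, 0.192 and 0.0616). Those for MHC class II, p53 and mesenchymal transition genes were lost without SACC replicate 2 (0.155, 0.152 and 0.06), and that for erythroid genes without SACC replicate 1 (0.131) or control replicate 2 (0.0776). The interferon call was also lost with each array centred on its median (0.0553). With only probe sets above the median probe set, the calls for lymphoid stromal, p53, interferon and mesenchymal transition genes were lost (0.0696, 0.116, 0.102 and 0.106), and the erythroid list, mostly dim, was not among the lists tested. In fry, which asks whether a list's genes move on balance in a single direction, no list passed after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.0982, for macrophage and for dendritic cell genes.

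Pluripotency genes were set beside these lists because 1 SACC array came from ES medium. None of the 18 passed over all probe sets, 1 rose adjusted over the list alone, and the medians were -0.06 and 0.04. The core factor Pou5f1 lay between 2.36 and 3 on the 4 arrays, below the median of each, and 11 of the 18 genes were below the median on every array. Tbx3, which is also expressed in many mesenchymal tissues, had ratios of 1.38 and 2.17 (limma adjusted p 0.0718 after Benjamini-Hochberg adjustment).

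The next comparisons took each pair alone, where 1 array stood against 1 and no test was possible. In the ES pair, in which medium and cell state differed together, 3854 probe sets differed at least 2-fold, 2240 higher and 1614 lower in SACCs. The endopeptidase Mme had a ratio of 6.5 there and 0.77 in the plain pair, the angiotensin receptor Agtr2 5.6 and 0.28, and the osteoclast differentiation factor Tnfsf11 5.46 and 2.02. The controls of all 3 in the ES pair lay below the array's median, as did both plain pair values of Mme and the plain pair control of Tnfsf11, so these folds are uncertain. In the plain pair, in which both arrays had the same medium, 3893 differed at least 2-fold, 2111 higher and 1782 lower. The cytokines Lif (3.35) and Il6 (3.03) and the iron-binding lipocalin Lcn2 (3.94) were higher in SACCs of that pair, against -0.85, -0.59 and -1.15 in the ES pair. The fatty acid-binding protein Fabp7 was lower there (-3.1) and had a ratio of 0.95 in the ES pair.

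Of 39 lists, 10 had medians outside the central 95% of 10000 expression-matched random lists in both pairs and in the same direction. Fibroblast and matrix, smooth muscle, mesothelial and mesenchymal transition genes were higher, and macrophage, lysosome and lipid handling, MHC class II, erythroid, monocyte (medians -0.46 and -0.66) and adipocyte genes (-0.47 and -0.38) lower. Of the 7 adipocyte genes 4 lay below the median on every array. The remaining members, Pparg, Fabp4 and Lpl, are also on the lysosome and lipid handling list. Among the monocyte genes Cx3cr1, the fractalkine receptor, fell by 1.91 ± 0.16 (SE, n = 2 pairs), while Plac8 had ratios of 2.14 and 1.47.

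**Figure D3:**
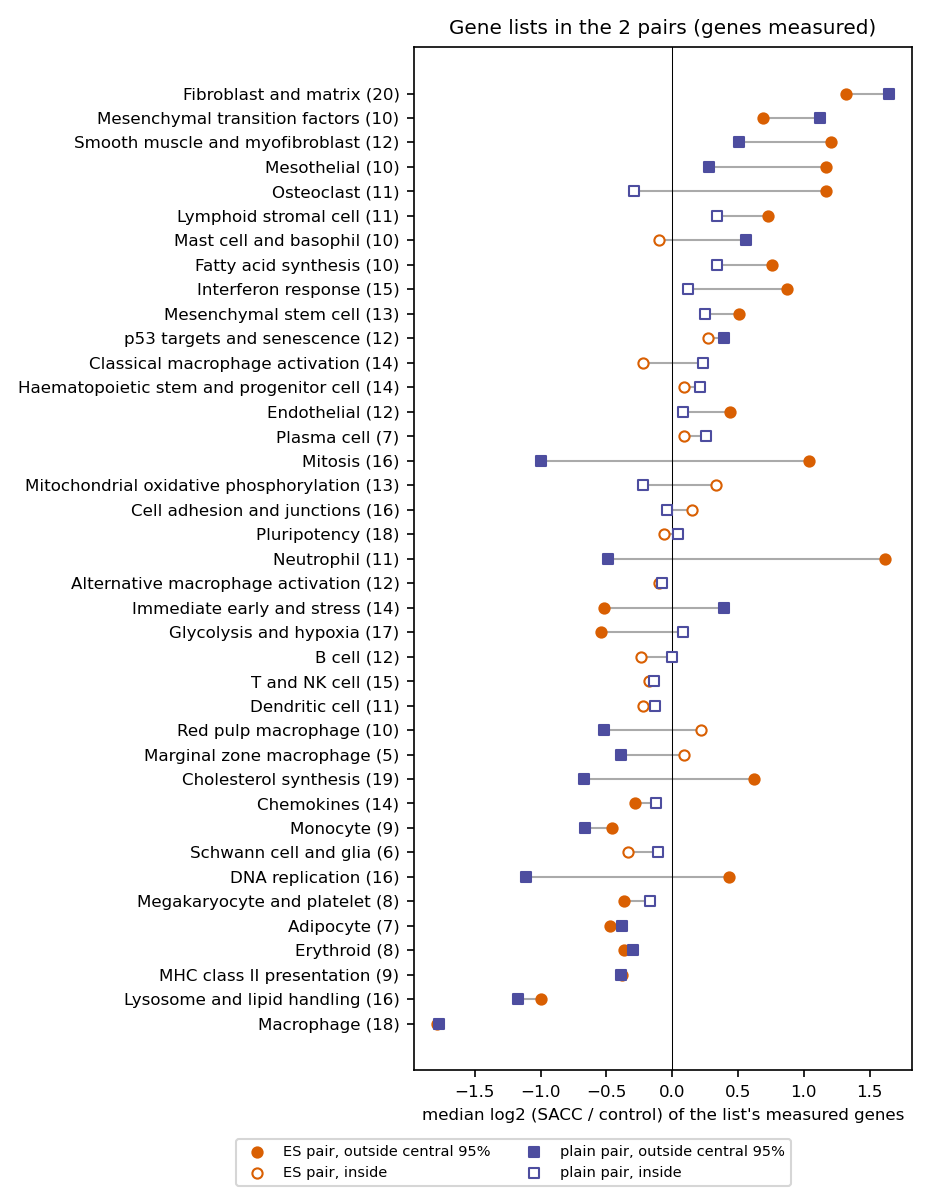
Median log2 ratio of SACC to control (x axis) of each of 39 gene lists (y axis, with the number of genes measured) in the ES pair (circles) and the plain pair (squares); filled symbols lie outside the central 95% of 10000 random lists matched on expression. Macrophage genes stand at the bottom (-1.79 and -1.77), fibroblast and matrix genes at the top (1.32 and 1.65), and mitosis genes lie on both sides of 0 (1.04 and -1).

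The last comparison asked where the pairs differed. Cell division genes went opposite ways: all 16 mitosis genes were higher in SACCs in the ES pair and lower in the plain pair, with medians of 1.04 and -1. Cyclin B2, Ccnb2, had ratios of 1.62 and -0.93, Plk1 1.6 and -0.45, and the proliferation marker Mki67 0.74 and -1.21. DNA replication genes had medians of 0.43 and -1.11, opposite in 13 of 16, and Pcna had ratios of -0.27 and -2.04. Cholesterol synthesis genes had medians of 0.62 and -0.67, opposite in 16 of 19. None of these 3 lists had a member past limma's test over both pairs or adjusted over the list alone, and camera's Benjamini-Hochberg adjusted p were 0.726, 0.229 and 0.662. Without the pair block, camera called mitosis genes lower on leaving out control replicate 1 (adjusted p 0.000893) and higher on leaving out control replicate 2 (1.21e-05). The control arrays differed as well: the median log2 difference of mitosis genes was -1.49 for the control of the ES pair minus that of the plain pair and 0.58 for the SACC arrays in the same order, each less the median of all probe sets, across tables that appear normalized separately.

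**Figure D4:**
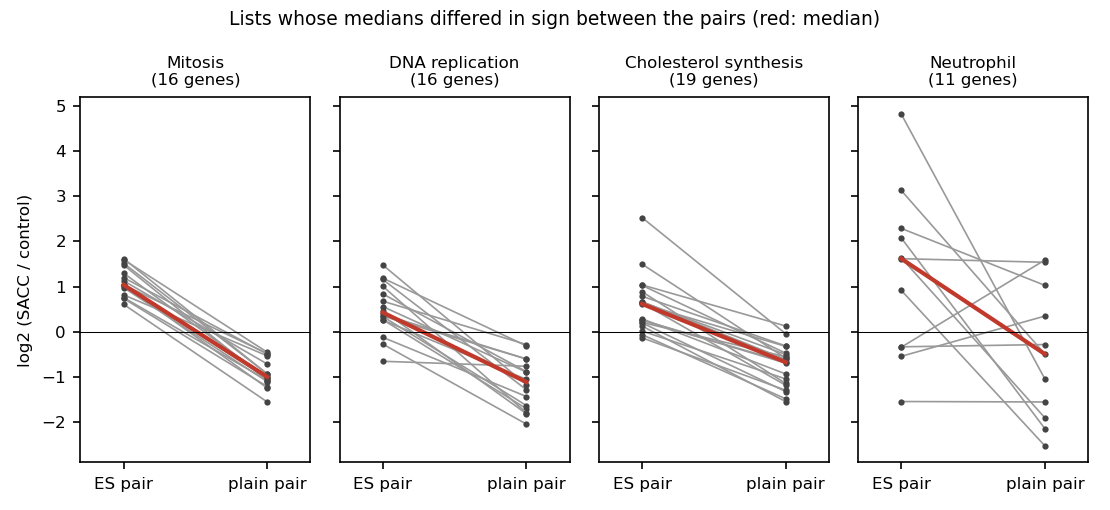
Log2 ratio of SACC to control (y axis) of each member of 4 lists in the ES pair and the plain pair (x axis); grey lines join the values of a gene and the red line joins the medians. The 16 mitosis genes all cross 0 from the ES pair to the plain pair, while the 11 neutrophil genes spread from 4.82 (S100a9) to -1.54 (Csf3r) in the ES pair.

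Neutrophil and immediate early genes also had medians of opposite sign outside the random range, 1.62 and -0.49 for the former and -0.52 and 0.39 for the latter. The calcium-binding S100a9 had ratios of 4.82 and -1.04, and 5 of 11 neutrophil genes were higher in the ES pair and lower in the plain pair. The cathelicidin Camp rose by 1.58 ± 0.16 (SE, n = 2 pairs) and Csf3r, the granulocyte colony-stimulating factor receptor, fell by 1.54 ± 0.16; adjusted over the list alone 2 rose and 1 fell. Camera gave the neutrophil list a Benjamini-Hochberg adjusted p of 0.662 and direction up, with a mean of 0.38 and a median of -0.03 over both pairs. Without the pair block, camera called the list lower on leaving out control replicate 1 (Benjamini-Hochberg adjusted p 0.00415) and higher on leaving out control replicate 2 (0.000228). Among the immediate early and stress genes the transcription factor Atf3 fell by 2.7 ± 0.27, 1 member rose and 4 fell adjusted over the list alone, and Egr1 had ratios of -1.35 and 1.25; camera's adjusted p was 0.662. In all, 385 probe sets had ratios at least 4-fold apart between the pairs, 234 with the ES pair above and 151 below. In 205 of them (53.2%) the 2 control arrays lay further apart than the 2 SACC arrays, across tables that appear normalized separately. The medium of the SACC array and the pair cannot be told apart, and these differences were not tested.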

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

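The comparison of the macrophage genes in the plain pair and those of fibroblast with smooth muscle and endothelial genes were tests chosen after the result was seen, as were the reading of the neutrophil test and that of the primary granule genes by pair; the other tests were written before their results were seen. Among 188 named entries, 9 genes differed at least 2-fold in opposite directions in the 2 pairs, a difference that was not tested because each pair has 1 array per group. All 9 were among the genes named for large differences between the pairs, so the naming rule favoured them. Over all probe sets, 46 were at least 2-fold higher in the ES pair and lower in the plain pair, and 19 the reverse. Independent pairs would give 88.6 and 75.7, so such opposite differences were fewer than that. The ratio in the ES pair minus that in the plain pair was 5.86 for S100a9, 5.24 for Stfa2l1, 4.33 for the acid phosphatase Acp5, 4.22 for the granule protein Ngp and 3.98 for the chitinase-like Chil3. It was -3.44 for the chemokine Cx3cl1, -3.47 for the vasodilator peptide Adm, -4.28 for the bone morphogenetic protein Bmp2 and -5.09 for Lcn2. In the ES pair the control values of S100a9, Stfa2l1, Ngp and Chil3 lay below the array's median, as did the SACC value of Chil3. The plain pair control of Bmp2 did so too, so these differences are uncertain in size.

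The opposite shift of macrophage and fibroblast genes was weighed first. After quantile normalization over the 4 arrays the macrophage median nearer 0 was -1.78. The sorted values of any 2 arrays differed by at most 0.32, so this step could not move the median far and cannot test the authors' scaling. The plain pair, with the same medium on both arrays, had a median of -1.77, which argues against ES medium as the cause. A lower share of leukocytes in the SACC arrays may account for the macrophage genes. Of 24 pan-leukocyte genes, none of them on the earlier lists, 23 were lower in both pairs, and their median in the pair nearer 0 was -1.86. The abundant Laptm5 lay at 10.5 and 10.45 on the SACC arrays against 12.78 and 11.85 on the controls, while Lsp1 was higher in both pairs. Ptprc, a member of this set, had been among the genes named in any case. Macrophages are leukocytes themselves, so this set cannot tell fewer leukocytes from lower levels of these genes within macrophages. A lower leukocyte share alone would raise all stromal genes alike. In the plain pair, fibroblast genes exceeded the abundant smooth muscle genes by a difference of medians of 1.21, more than the SDs across the genes of the 2 sets (0.48 and 0.4). This argues against a lower leukocyte share as the only source there, for 1 array against 1 and with no replicate check. In the ES pair they differed by 0.14 and it cannot be told apart there, since the 4 endothelial genes, which the fibroblast genes exceeded by 0.96 and 1.46, lay close to the array medians and decide nothing. Whether matrix genes also differ per stromal cell, through the colony state that the labels name, stays open and was not tested. The gap alone cannot tell that from a different mix of stromal cells.

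For the mitosis genes, the medium of the SACC arrays alone would leave the controls alike, but the control of the ES pair minus that of the plain pair gave a median of -1.49 less that of all probe sets, across tables that appear normalized separately. Quantile normalization over the 4 arrays left medians of 0.99 and -0.98. With sorted values at most 0.32 apart it could not have moved them far, so it cannot test the authors' scaling. Why the controls differed stays open. An effect of the medium on the SACCs themselves stays possible and was not tested, because the medium and the pair coincide.

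For the neutrophil genes, neutrophils in the SACC array of the ES pair and in the control of the plain pair may have been a source. Of 20 further neutrophil markers, none of them on the earlier lists, 15 were above an array's median, and their median in the pair nearer 0 was -0.02; over all 20 the medians were -0.04 and -0.21. That value met the limit set in advance against this source, but the limit was a poor choice, because members went both ways with SDs of 1.51 and 1.59: Slpi had ratios of 2.92 and 2.93, Hp 3.8 and 1.87, Lcn2 -1.15 and 3.94, and Stfa2l1 2.6 and -2.64, and macrophages or stromal cells also express several of them. The source therefore cannot be told apart from other ones for these genes. Whether myeloid progenitors stood in place of late neutrophils cannot be told apart either. The limit first set, changed after the values were seen, asked the 5 primary granule genes, 2 of them also on the neutrophil list, to move with that list. That was wrong, since such a replacement of cells moves the granule genes against it. In the plain pair they did so, all 5 higher in SACCs (median 1.48, SD 0.58) against -0.49 for the neutrophil list, but this was read after the values were seen and the members of that list went both ways (SD 1.48). In the ES pair the median was -0.34 (SD 0.59), only Prtn3 lay above an array's median, and its ratio was 0.88.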

How the results depend on the processing

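The adjusted p of 0.04 was a setting chosen after the result was seen, and the other settings were planned. The count of 587 probe sets over both pairs changed with every setting. It was 0 with no replicate block (limma; 3497 at an unadjusted p under 0.05), 0 with each array centred on its median (7405 unadjusted, none of the 587 shared) and 0 at an adjusted p of 0.04 (7608 unadjusted). It was 0 to 0 on leaving out each of the 4 arrays in turn without the replicate block (2264 to 3535 unadjusted), a fit in which the lone array of a group is assumed to vary like the other group. With quantile normalization over the 4 arrays it was 2045, with probe sets above the median probe set 1326, with a trend 898, with robust eBayes 2623, with 1 probe set per gene 1027 and at an adjusted p of 0.10 2188. The calls with quantile normalization, trend and robust eBayes held all 587. The smallest adjusted p was 0.0476 as planned, 0.0636 after centring, 0.0123 after quantile normalization and 0.0013 with robust eBayes; small changes of scale decide whether any probe set passes, and a limma fit with 1 residual degree of freedom has little to say about single genes near the threshold. All 12 gene lists called with the replicate block were called without it, where 13 passed; the list gained was that of adipocyte genes, lower (adjusted p 0.0335), and the mean of a gene's probe sets (0.0369) and probe sets above the median probe set (0.0439) gained it too, against 0.0758 as planned. On leaving out an array 11 to 16 lists passed, and of the 12 these held 11 without SACC replicate 1, 8 without control replicate 1, 9 without SACC replicate 2 and 11 without control replicate 2; the fibroblast, smooth muscle, mesothelial, fatty acid, macrophage and lysosome lists were in each. Camera with an estimated correlation called 0 lists, on an estimate from 1 residual degree of freedom. At 1.5-fold and 4-fold, 4248 and 287 probe sets differed in the same direction in both pairs, 9642 and 775 in the ES pair and 8310 and 722 in the plain pair, by construction of the limit. Pearson's r between the pairs was 0.663 among probe sets above the median probe set; the cause was not tested there, nor for the counts above. Centring and quantile normalization left the counts of 2-fold differences and of 4-fold differences between pairs within 1.5 times of the planned values. The lists outside the random range in both pairs were 10 as planned, 10 after quantile normalization and 8 with probe sets above the median probe set; centring was not run for them. No named gene past its threshold turned its direction. With centring, without the block and on leaving out an array no gene passed, so none could turn there. Quantile normalization changed the values too little to turn ratios of that size, so the lack of turns says little. Without the block, camera called neutrophil and mitosis genes lower on leaving out control replicate 1 (adjusted p 0.00415 and 0.000893) and higher without control replicate 2 (0.000228 and 1.21e-05), and glycolysis and hypoxia genes higher without SACC replicate 1 (0.0363) and lower without SACC replicate 2 (0.000588); with all 4 arrays none of these was called. Lists that gained a call in a single direction on leaving out an array were red pulp macrophage, monocyte, megakaryocyte, adipocyte, DNA replication, cholesterol synthesis and immediate early genes, lower, and mast cell and mesenchymal stem cell genes, higher. All 48 named entries past the test lost it after centring, without the block and on leaving out an array, kept it after quantile normalization, and 45 kept it with the mean of a gene's probe sets. Folds of dim probe sets are uncertain, since no detection calls were used.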

Other observations

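The melanocyte list was a test chosen after the result was seen. Some melanocyte genes had high values in the control of the ES pair. Pmel, a structural protein of melanosomes, lay at 8.62 there and at 5.13 on the SACC array of the pair, and Mlana at 7.31 and 3.56; their ratios in the plain pair were 0.42 and -0.05. A list of melanocyte genes without these was then written, and 10 of them were measured. In the control of the ES pair the pigment enzymes Dct and Tyrp1 lay at 8.02 and 7.07 and the endothelin receptor Ednrb at 9.38, while 4 of the 10, Oca2, Gpr143, Trpm1 and Mc1r, lay below the array's median (4.25, 3.38, 3.25 and 4.27). On the control of the plain pair Dct, Tyrp1 and Ednrb lay at 4.38, 4.32 and 7.08, in a table that appears normalized separately. The 10 genes, none of them on the earlier lists, had medians of -1.38 in the ES pair and -0.28 in the plain pair. Mitf, which macrophages and osteoclasts also express, had ratios of -1.49 and -1.14, and Mc1r, the melanocortin receptor, -0.22 and 0.31.

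Chemokine genes moved in both directions. Cxcl3 and Cxcl5, ligands that draw neutrophils, rose, and Ccl9 fell by 1.54 ± 0.16 (SE, n = 2 pairs); adjusted over the list alone 4 of 14 rose and 5 fell. Cxcl2, a close relative of Cxcl3, had ratios of -2.97 and -1.14, and Ccl3 -3.24 and -0.45. The list's medians were -0.28 and -0.12 and its mean 0.21, and it was the only list past fry's test of change in either direction (Benjamini-Hochberg adjusted p = 0.0112), with a camera adjusted p of 0.845. Arg1, which alternatively activated macrophages and some stromal cells express, rose by 1.68 ± 0.16, while Clec7a of the same list fell by 2.25 ± 0.16; adjusted over the list alone, 1 of the 12 alternative activation genes rose and 2 fell (medians -0.1 and -0.08, camera adjusted p = 0.608). Osteoclast genes had medians of 1.17 and -0.29 (camera adjusted p = 0.524). The collagen-degrading protease Ctsk had ratios of 3.23 and 0.23, while Tnfrsf11a, the receptor of the Tnfsf11 product, fell by 1.64 ± 0.17; adjusted over the list alone 3 of 11 rose and 2 fell.

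None of the lists that follow was called by camera in the planned fit after Benjamini-Hochberg adjustment. Red pulp macrophage genes had medians of 0.22 and -0.52 (adjusted p = 0.233) and marginal zone macrophage genes of 0.09 and -0.39 (0.749), with the scavenger receptor Marco at ratios of 0.93 and 2.72. Classical activation genes had medians of -0.22 and 0.23 (0.709), monocyte genes a camera adjusted p of 0.209, and dendritic cell genes medians of -0.22 and -0.13 (0.216), with Itgax at -3.03 and -4.9. B cell genes had medians of -0.24 and 0 (0.435), T and NK cell genes of -0.18 and -0.14 (0.14) and plasma cell genes of 0.09 and 0.26 (0.573), where Prdm1 fell by 1.93 ± 0.19 and the stromal and epithelial proteoglycan Sdc1 had ratios of 2.54 and 1.58. Mast cell and basophil genes had medians of -0.1 and 0.56 (0.181), megakaryocyte and platelet genes of -0.37 and -0.17 (0.154), and haematopoietic stem and progenitor genes of 0.09 and 0.21 (0.193), with Tal1 at -3.55 and -1.55 and Meis1, also a gene of mesenchyme, at 1.87 and 2.65. Mesenchymal stem cell genes had medians of 0.51 and 0.25 (0.0839), and Nt5e, the surface enzyme CD73, rose by 1.69 ± 0.16. Endothelial genes had medians of 0.44 and 0.08 (0.626) and Schwann cell and glia genes of -0.34 and -0.11 (0.154). Adipocyte genes had a camera adjusted p of 0.0758, although they were called lower without the pair block (0.0335), with the mean of a gene's probe sets (0.0369) and with probe sets above the median probe set (0.0439). Their members above an array's median are all shared with the lysosome and lipid handling list. Glycolysis and hypoxia genes had medians of -0.54 and 0.08 (0.524, but called higher without SACC replicate 1 at 0.0363 and lower without SACC replicate 2 at 0.000588, both without the pair block), adhesion and junction genes of 0.15 and -0.04 (0.491), and mitochondrial oxidative phosphorylation genes of 0.33 and -0.22 (0.743). The camera adjusted p of the pluripotency list was 0.906.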
